A study of Phyllotreta striolata with 15 samples.

How the data were processed

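RNA was measured in whole bodies of the striped flea beetle, Phyllotreta striolata, a leaf beetle that feeds on crucifers. The 15 libraries fall into 5 groups of 3, which are eggs, larvae, pupae, male adults and female adults. Group and replicate number were taken from the sample titles. Per the labels' protocols, total RNA was extracted with TRIzol and libraries were made with an Illumina TruSeq RNA kit. The submitters' processing notes name fastp, HISAT2 and featureCounts. Their versions and settings, the strand setting and the genome build are not given in the sources used here.

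The authors deposited 3 tables. One holds read counts per gene as the authors deposited them, not normalized and made with featureCounts from HISAT2 alignments as far as the submitters' processing notes name tools, for 11862 genes in each library, and every column was matched to a sample through its library name. The second holds the authors' TPM (a length-scaled share of transcripts), already averaged over the libraries of each group, so it gives no spread. The third lists gene identifiers that the authors put forward as specific to a stage or sex, 1129 in 5 lists with no gene in more than 1 list and no numbers. The rule behind these lists is not given in the sources used here. Tested on the TPM table, each listed gene had a mean TPM of at least 2 in its group and at least 5 times that of the highest other group. This rule returned the deposited lists exactly for eggs, larvae and female adults, and 2 further genes each for pupae and male adults. The log2 ratios between groups in the TPM table followed those of the counts, with Pearson's r across genes from 0.999 to 1.000 in the 3 comparisons of single groups.

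The files identify genes only by protein-style identifiers and do not pair them with gene names, and no annotation was used here. The 27 lists of gene families and tissues that had been fixed before the data were examined, matched on gene names, could therefore not be tested, nor could the named sex-determination genes. Gene groups in the text are the authors' 5 lists and the genes called in the comparisons. Without names, genes from near-identical families cannot be recognised, and single genes may share reads with a copy.

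Library totals ran from 16509113 to 32598781 counts. Counts were filtered with edgeR's filterByExpr at its default settings, which left 11440 genes and dropped 422. Libraries were scaled by TMM, and CPM below means a library's counts scaled to a fixed total on that scale, unless stated otherwise. The main test was edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3, robust fit) with all 15 libraries in one model of 5 groups and no other term. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested and a fold change of at least 2. Standard errors were not reported for genes with no counts on one side. For these, the fold is a lower bound against 3 counts summed over the libraries of that side, and bounds cover counting error only. A gene was called specific to a group when it was called higher there than in each of the other 4 groups. Named genes are, per comparison, the 2 with the largest rise and the 2 with the largest fall among called genes with no overlap of library values and a mean of at least 10 CPM in the higher side. This was the rule set for data without gene names.

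Simulated counts with the real library sizes and dispersions were used to test the pipeline, with 200 genes changed per simulation. Each gene's real mean was evened out over the compared groups, or over all 5 groups for specific genes, before the change. Changed genes were drawn only from genes above a minimum of expected counts, so the shares below do not cover genes with low counts. For female against male adults, 7.46% of genes changed 2-fold, 35.8% of those changed 4-fold and 65.2% of those changed 8-fold were called, and 3 unchanged genes of 11377 tested were called. In the stage comparisons 4.48% to 8.96% of 2-fold changes and 72.7% to 74.2% of 8-fold changes were called. For specific genes, 40.3% to 52.2% of 4-fold rises were recovered, with 0 unchanged genes called. A gene left uncalled is therefore not shown to be unchanged, even at folds of 4 or 8. Far more genes passed in the data, with 4226 at an adjusted p under 0.05 (edgeR) for sex alone. This makes the Benjamini-Hochberg cutoff looser than in the simulations. The shares above hold for the simulated setting and may understate recovery in the data.

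No 2 columns were identical, and replicate pairs differed by far more than sampling noise, with a chi-square per degree of freedom of at least 86.6 within groups, so no library was counted as a copy of another. The series' design text calls the replicates biological, but no label says whether they came from separate cultures or collections, so p-values measure the spread between these samples, which may be partly technical. Replicate numbers are shared between groups, but no label ties same-numbered samples together, and the samples were treated as unpaired. The column names of the count table carry 3 prefixes, one on all pupal libraries, one on all egg libraries and one on larvae, male and female adults. Their meaning is not given in the sources used here. If they mark batches, the batch cannot be told apart from the group in any comparison of eggs or pupae with another group, while female against male adults lies within one prefix.

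Alternatives fixed before the data were examined were DESeq2 size factors, library size alone, no filter and a stricter filter on low counts, DESeq2 1.42.0, the replicate number as a block, other fold minimums, fits on the compared groups alone, a tau index of specificity and leaving out each library in turn.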

Results

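Transcript levels of 11862 genes were measured in eggs, larvae, pupae, male adults and female adults of P. striolata, with 3 libraries per group. Egg libraries held 23135342 to 26690102 counts, larval libraries 16509113 to 29806307, pupal libraries 29280435 to 32598781, male adult libraries 18015995 to 23367276 and female adult libraries 19371626 to 21399593. Male adults used the widest set of genes, with 10566 ± 59.4 genes at 1 CPM or more (SD, n = 3), followed by pupae with 10263 ± 48.4, and eggs used the narrowest, with 8604 ± 352. In these numbers of genes, CPM was taken on the library totals without TMM. The 10 most abundant genes took between 4.98% and 10.6% of a library's counts. The study set out to find genes whose expression marks a developmental stage or a sex.

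Replicates of pupae were the most alike, with Spearman's rho across genes from 0.979 to 0.986, and those of female adults ranged from 0.957 to 0.979. Egg replicates ranged from 0.936 to 0.966. Male adult replicates ranged from 0.897 to 0.977, with the lowest value between male adult replicates 1 and 2. Larvae were the most variable group. Larva replicates 2 and 3 had a rho of 0.958, but larva replicate 1 reached only 0.852 and 0.821 with them. Larva replicate 1 had a rho of 0.709 to 0.795 with male and 0.654 to 0.669 with female adult libraries. In larva replicates 2 and 3 the order was the other way, with 0.546 to 0.704 for male and 0.775 to 0.807 for female adult libraries. On the first principal component, larva replicate 1 lay at -104, on the side of the male adults and pupae, and the other 2 larval libraries at 46.7 and 41.8, on the side of the female adults and eggs. The libraries' column names carry 3 prefixes, one for eggs, one for pupae and one for larvae and adults, so that in the stage comparisons below a difference between prefixes and a difference between stages cannot be told apart.

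**Figure D1:**
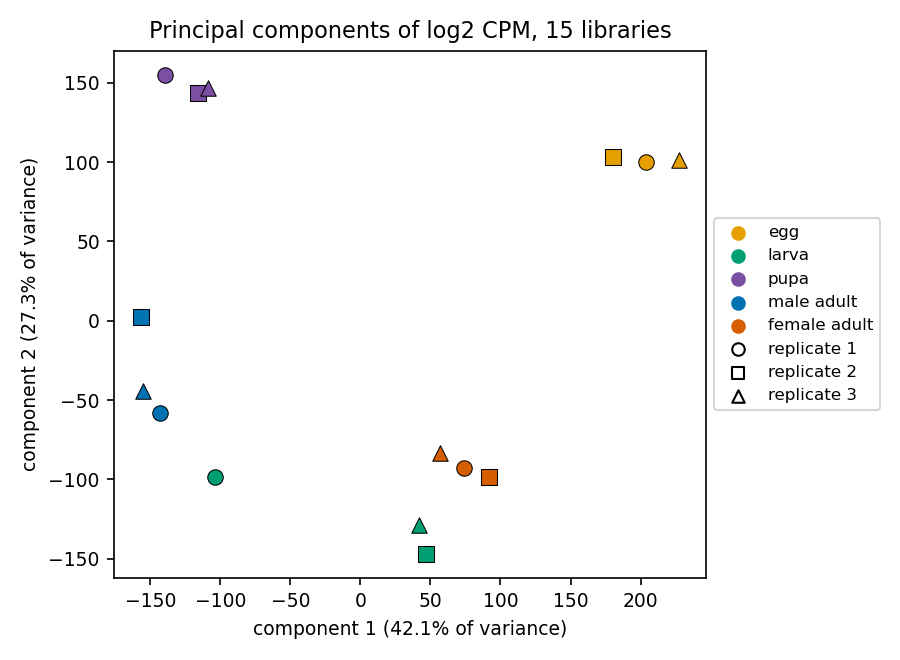
Principal components of log2 CPM, with each point a library, colours for the 5 groups and marker shapes for the replicate number. Component 1 holds 42.1% and component 2 holds 27.3% of the variance, and larva replicate 1 lies apart from the other 2 larval libraries, at -104 on component 1 against 46.7 and 41.8.

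Female and male adults were compared to find genes with sex-biased expression. Of 11440 genes tested, 1342 were higher in females and 1820 were higher in males (edgeR's quasi-likelihood test, adjusted p under 0.05 and at least 2-fold). Male bias was the more extreme: genes called higher in males had a median log2 change of -4.56, and genes called higher in females one of 1.51, with genes absent from one sex set at their lower bound. Differences of 8-fold or more (log2 of 3) were found for 1066 male-biased and 207 female-biased genes. Of the called genes, 344 male-biased ones had no count in any female library, and 30 female-biased ones had none in any male library.

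In male adults CAG9854698.1 had the highest mean CPM of all genes, 21705 ± 4281 (SD, n = 3). It had 2 counts in all female libraries together, a ratio of 840509 with an exact Poisson interval from 232677 to 6940352 that covers counting error only (adjusted p = 1.06e-05, edgeR). CAG9853954.1 reached 5568 ± 2005 CPM in males and no count in females, at least 143732-fold higher in males (adjusted p = 0.000346, edgeR). Both are on the authors' male list. In females, CAG9858241.1 reached 1528 ± 907 CPM and had no count in males, at least 31785-fold higher (adjusted p = 0.00348, edgeR), and it is on none of the authors' lists, as eggs held it at 5785 ± 4399 CPM. CAH1185589.1 reached 415 ± 258 CPM in females against no count in males, at least 8637-fold higher (adjusted p = 0.000129, edgeR), and is on the authors' female list. Of the authors' male-specific genes, 162 of 169 tested were called higher in males. Of their female-specific genes, 74 of 86 were called higher in females. Adjusted over the list alone, these counts were 167 and 80. The authors chose these lists on the same libraries, so the counts are not independent evidence of direction. Of the authors' pupal genes, 57 of 480 were called higher in males and 7 higher in females. Over all 11440 genes tested the numbers were 1820 and 1342, so neither bias was more common in the pupal list.

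The 965 genes with a male bias of 16-fold or more were followed through the other libraries. Between 98.2% and 99.1% of them reached 1 CPM in each male library, and 10.5% to 13.7% did in each female library, from which the set was defined. In pupae 82.1% to 85.3% reached 1 CPM, at library medians of 9.54 to 17.7 CPM. In eggs only 13.7% to 17.8% did. Larval libraries differed from each other: 87.3% of the genes reached 1 CPM in larva replicate 1, at a median of 22.6 CPM, against 12.8% and 14.9% in larva replicates 2 and 3, at medians of 0 CPM. The 117 genes with a female bias of 16-fold or more reached 1 CPM in 73.5% to 79.5% of cases in eggs, 47.9% to 53.8% in pupae and 35.9% to 43.6% in larvae, against 35.04% to 38.5% in males.

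**Figure D2:**
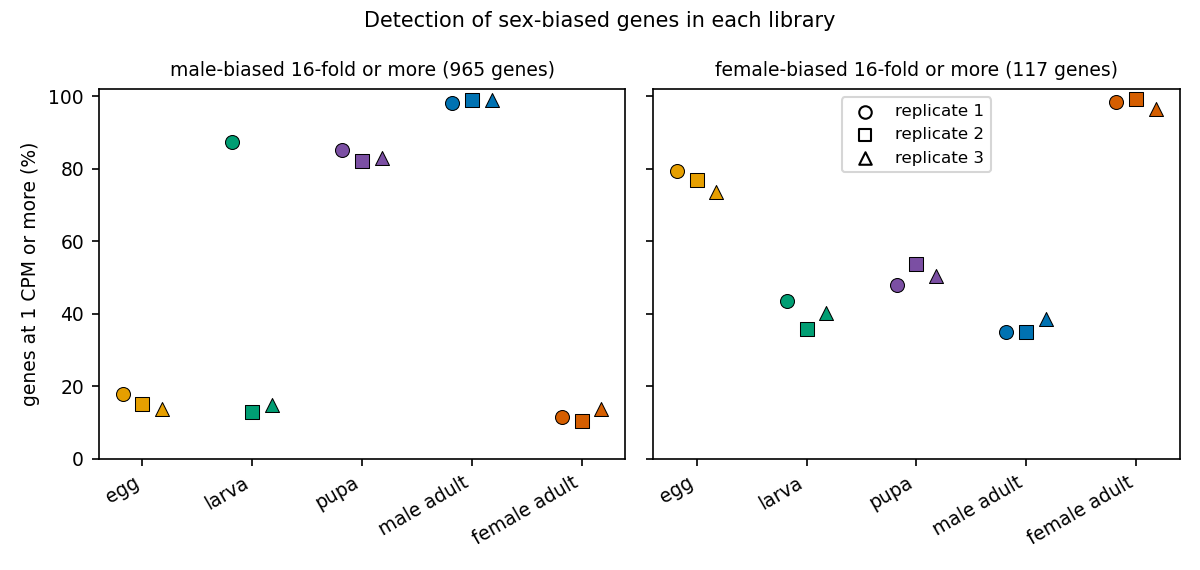
Share of sex-biased genes at 1 CPM or more (y axis, %) in each library, by group (x axis), for 965 male-biased genes (left) and 117 female-biased genes (right) with a bias of 16-fold or more in adults. Points are single libraries with marker shapes for the replicate number, and larva replicate 1 lies at 87.3% in the left panel while larva replicates 2 and 3 lie at 12.8% and 14.9%.

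The split between female-biased and male-biased genes depended on scaling. Under TMM, 42.4% of called genes were higher in females, and with library size alone 60.4% were. The median log2 change of all genes moved from -0.23 to 0.09 with this choice, so small shifts have no firm sign. With library size alone, 2121 genes were called higher in females and 1389 higher in males. The split also moved with larva replicate 1, which is on neither side but shares the fit. Without it 1672 genes were called higher in females and 1786 higher in males, and 1663 of the 1820 male-biased genes were still called.

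Larvae were compared with eggs to find genes that differ between these stages. Among the 4 comparisons this one had the most calls: 6773 of 11440 genes were called, 3651 higher in larvae and 3122 higher in eggs. Genes higher in larvae rose by a median log2 of 4.20, with genes absent from eggs at their bound, and 313 of them had no count in any egg library. Genes higher in eggs fell in larvae by a median log2 of -1.87. Changes of 8-fold or more numbered 2387 towards larvae and 520 towards eggs.

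CAG9863956.1 reached 6414 ± 1259 CPM in larvae (SD, n = 3) and no count in eggs, at least 176756-fold higher (adjusted p = 1.84e-06, edgeR), and CAG9858250.1 reached 5554 ± 2689 CPM, at least 153051-fold higher (adjusted p = 9.97e-05, edgeR). Both are on the authors' larval list, of which 221 of 222 tested genes were called higher in larvae. Among genes higher in eggs, CAG9858241.1, the female-biased gene named above, was at 5785 ± 4399 CPM in eggs and at no count in larvae, at least 100848-fold higher in eggs (adjusted p = 0.000626, edgeR). CAG9857233.1 was at 1266 ± 543 CPM in eggs, at least 22072-fold higher than in larvae (adjusted p = 8.72e-06, edgeR), and 4 counts were found over all adult libraries and 0 in pupae. It is on the authors' egg list, of which 151 of 156 tested genes were called higher in eggs.

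Part of this change followed larva replicate 1. Of the 1820 male-biased genes, 1087 were called higher in larvae than eggs with all libraries and 502 without that library. For the 965 with a male bias of 16-fold or more, the numbers were 652 and 98. The median changes and the numbers of 8-fold changes were not computed without larva replicate 1 and may rest on it in part. Without larva replicate 1, 2968 genes in all were called higher in larvae and 3405 higher in eggs, which turns the balance of directions. With library size alone 41.2% of calls were higher in larvae, against 53.9% under TMM, and the median of all genes moved from a log2 of 0.02 to -0.49. The numbers were 2963 higher in larvae and 4234 higher in eggs.

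Pupae were compared with larvae to find genes that differ between these stages. Of 4654 genes called, 2328 were higher in pupae and 2326 lower. The median log2 change was 2.34 for genes that rose, with absent genes at their bound, and -2.33 for genes that fell. The authors' pupal list took 20.8 ± 2.48% of the counts of pupal libraries (SD, n = 3) and 0.513 ± 0.111% of larval ones, and 460 of its 480 tested genes were called higher in pupae. The larval list took 17.7 ± 1.83% of larval counts and 0.450 ± 0.136% of pupal counts, and 221 of 222 tested genes were called lower in pupae.

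CAG9860654.1 reached 6262 ± 1089 CPM in pupae (SD, n = 3) and had no count in larvae, at least 109177-fold higher (adjusted p = 0.000154, edgeR). It had no count in adults either. CAG9858191.1 was at 4336 ± 1714 CPM in pupae, at least 75585-fold higher than in larvae (adjusted p = 0.000319, edgeR). A pair of larval genes had no count in pupae: CAG9863099.1, at 3614 ± 1602 CPM in larvae and at least 99467-fold higher there (adjusted p = 2.11e-05, edgeR), and CAG9856627.1, at 2950 ± 1003 CPM and at least 81183-fold higher (adjusted p = 2.48e-05, edgeR). All of these are on the authors' pupal or larval list.

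Larva replicate 1 also weighed on this comparison. With all libraries, 367 of the 1820 male-biased genes were called higher in pupae than larvae, and without larva replicate 1 the number was 1187. The total then was 5400 genes, 3203 higher in pupae and 2197 lower.

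**Figure D3:**
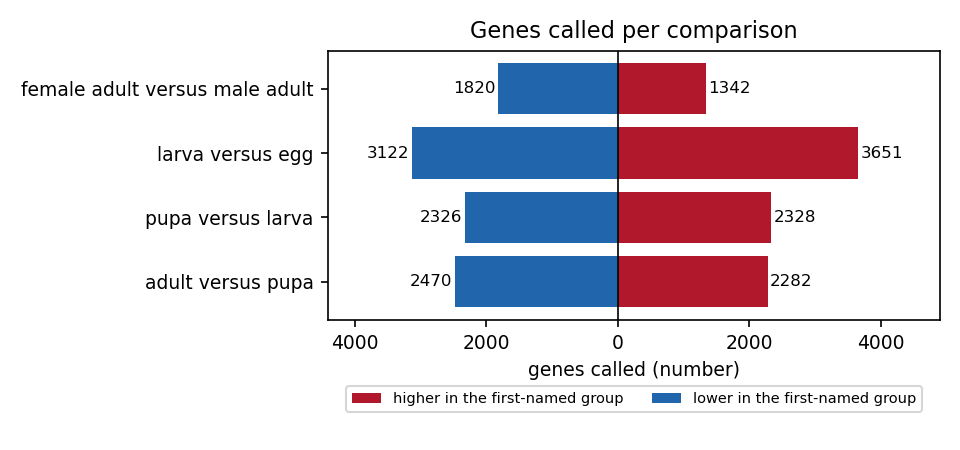
Number of genes called (x axis) in each comparison (y axis), with genes higher in the first-named group drawn as bars to the right and lower ones to the left, from 11440 genes tested. Larva against egg has the most calls, 3651 and 3122, and female against male adults the fewest, 1342 and 1820.

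Adults, taken as the mean of both sexes, were compared with pupae. Here 2282 genes were higher in adults and 2470 were lower, with a median log2 change of 2.03 for genes that rose and -2.55 for genes that fell. Of the authors' pupal genes, 476 of 480 were called lower in adults. The authors' male list had 43 of 169 genes called higher in adults and 1 lower, and their female list 45 of 86 higher. Of their larval genes, 76 of 222 were called higher in adults than in pupae and 37 lower. The direction of the majority depended on scaling, with 48.02% of called genes higher in adults under TMM and 62.6% with library size alone, 3120 higher and 1868 lower. The median log2 change of all genes moved from -0.09 to 0.28. Larva replicate 1 is on neither side of this comparison, but without it 2350 genes were called higher in adults and 2893 lower, and of the 1820 male-biased genes 1002 were called lower in adults, against 640 with all libraries.

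CAG9861310.1 had no count in pupae and 736 ± 436 CPM in adults (SD, n = 6), at least 20258-fold higher (adjusted p = 7.96e-06, edgeR), with 1091 ± 310 CPM in males and 381 ± 39.5 CPM in females. CAG9854681.1 had no count in pupae and 203 ± 181 CPM in adults, at least 5581-fold higher (adjusted p = 0.000357, edgeR), and single adult libraries ranged from 4.60 to 524 CPM. In the other direction, CAG9860654.1, the pupal gene named above, was at least 291929-fold lower in adults (adjusted p = 3.22e-05, edgeR). CAG9859844.1 fell from 1450 ± 610 CPM in pupae to no count in adults, at least 67594-fold lower (adjusted p = 5.87e-06, edgeR).

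Each sex was also set against pupae. Female adults differed from pupae in 5752 genes and male adults in 4075. In 86 genes the sexes moved in opposite directions, with a difference between the sexes that itself passed the test: 52 were higher in females and lower in males than in pupae, and 34 were the reverse. Opposite calls against pupae already set the sexes apart in the same fit, so the test between the sexes adds little. Larva replicate 1 is on neither side of these contrasts but shares the filter, the scaling and the estimate of spread, and without it this count was 356, of which 284 were higher in males and lower in females.

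Genes specific to one group were counted to meet the stated aim of the series. A gene counted when it was called higher in that group than in each of the other 4. Eggs had 952 such genes, pupae 833, larvae 568, male adults 215 and female adults 96, together 2664 genes or 23.3% of those tested. This order depended on the definition. At a minimum log2 change of 2, pupae had 519, larvae 314, eggs 245, male adults 121 and female adults 51, and at a tau of 0.8 or more pupae had 800, male adults 782, larvae 597, eggs 404 and female adults 129. With library size alone, larvae had 368 and female adults 187, and without a minimum fold eggs had 1589 and female adults 189. Specific genes took 29.6 ± 2.13% of counts in pupae (SD, n = 3), 28.6 ± 2.90% in larvae and 23.9 ± 2.51% in eggs. The share was 9.10 ± 1.86% in males and 4.38 ± 1.71% in females. A gene used by both sexes at similar levels cannot count for either, while each immature stage is 1 group, so the counts and shares of adults and immature stages are not comparable. Pupal genes stood out furthest from the other groups among the immature stages, with a median smallest log2 change of 2.53, against 2.20 in larvae and 1.47 in eggs. The corresponding medians were 2.65 for males and 2.08 for females. These are fitted values, which are no bound where a group has no counts.

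The authors' deposited table lists 160 genes for eggs, 226 for larvae, 481 for pupae, 175 for male adults and 87 for female adults. Of these, 146 egg, 211 larval, 440 pupal, 106 male and 55 female genes were also specific by the test used here. Independent lists of these sizes would share 12.98, 11.02, 34.95, 3.18 and 0.722 genes, and one-sided Fisher's exact tests across genes gave p-values of at most 4.29e-100. Both lists come from the same libraries, so a large overlap was built in. The test added 806 egg genes and 41 female genes to the authors' lists. It asks for 2-fold, while the authors' genes lay at least 5-fold above the highest other group in TPM. At a minimum log2 change of 2, 146 of 245 egg-specific genes were on the authors' list, and so were 51 of 51 female-specific genes. Among the authors' genes, 63 of 169 tested male genes and 31 of 86 tested female genes were not called against every other group. Male-specific genes numbered 479 without larva replicate 1, of which 186 were among the 215, and 135 and 134 without male adult replicate 2 and female adult replicate 2. Female-specific genes numbered 145 without egg replicate 1 and 51 without female adult replicate 2.

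**Figure D4:**
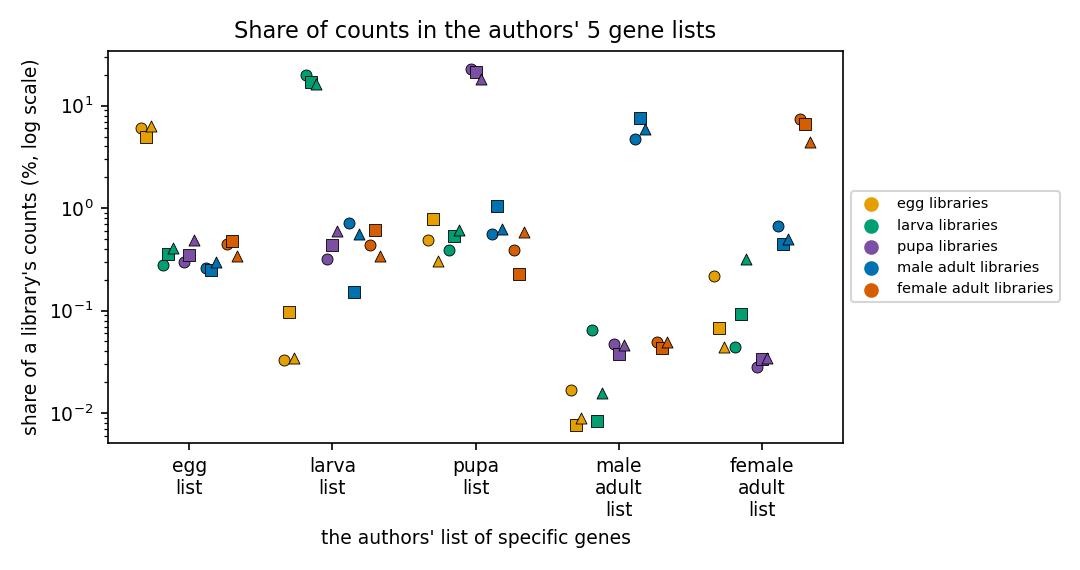
Share of each library's counts (y axis, %, log scale) that fell on each of the authors' 5 lists (x axis), with colours for the group of the library and marker shapes for the replicate number. Pupal libraries gave 18.1% to 23.02% of their counts to the pupal list and larval libraries 16.2% to 19.7% to the larval list, with larva replicate 1 the highest of these at 19.7%.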

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

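The count in this part and its alternatives were chosen after the data were seen. A set of 86 genes moved in opposite directions from pupae to female adults and from pupae to male adults, with a difference between the sexes that itself passed the test in each gene. Of these, 52 were higher in females and lower in males than in pupae, and 34 the reverse. The test between the sexes adds little here, since opposite calls against pupae in the same fit nearly guarantee it. The DESeq2 Wald test gave 129 such genes, of which 82 were among the 86, the replicate block gave 76 with 72 shared, and DESeq2 size factors in edgeR gave 86 with 78 shared. Library size alone also gave 86, but only 57 of them were the same genes, so the equal count does not show that the set was stable. Without larva replicate 1 the count was 356, with 85 shared. No biological explanation was tested for this set.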

How the results depend on the processing

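Leaving out libraries was planned, and its use to follow the male-biased genes and the genes that moved in opposite directions was chosen after the data were seen. Of the 226 alternative values for the counts of called and specific genes and the overlaps, 204 stayed within 1.5 times the main value. The 16 gene results named in the text kept their direction and call in all 384 combinations of gene result and alternative setting. They were chosen for extreme changes, so this says little about other calls. A minimum log2 change of 2 left 1678 genes for female against male adults, 4379 for larva against egg, 2729 for pupa against larva and 2692 for adult against pupa, and 245 egg-, 314 larva-, 519 pupa-, 121 male- and 51 female-specific genes, fewer by construction. Without a minimum fold there were 1589 egg-specific and 189 female-specific genes. With library size alone there were 368 larva-specific and 187 female-specific genes, and the cause was not tested. A tau of 0.8 or more, which ignores the spread between libraries, gave 404 egg- and 782 male-specific genes, and shared 168 male and 83 female genes with the authors' lists. Leaving out 1 library at a time gave 2205 to 3557 calls for female against male adults, 6100 to 6834 for larva against egg, 4237 to 5400 for pupa against larva and 4112 to 5243 for adult against pupa. Specific genes then ranged from 764 to 1265 in eggs, 416 to 676 in larvae, 726 to 898 in pupae, 134 to 479 in males and 51 to 145 in females, with the highest male count and the highest counts for pupa against larva and adult against pupa reached without larva replicate 1. The replicate numbers did not pair the samples: same-numbered deviations had a median correlation of 0.01, as had the others, with 4 of 30 same-numbered pairs over 0.1, and a library matched its own number best in 20 of 60 cases. With the replicate number as a block the 4 comparisons called 2973, 6197, 4527 and 4562 genes. Tests of the 27 gene lists, with estimated correlation or library size alone, were not run, since the genes have no names in the files.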

Other observations

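All tests in this part except the other splits of the libraries were chosen after the data were seen, and genes are not independent replicates in any of them. Female-biased genes were widely present in eggs. Of the 1342 genes called higher in female than in male adults, 73.5% were also called higher in eggs than in larvae, against 24.1% of the 8278 genes not called sex-biased, and 3.73% were called higher in larvae. Genes not called sex-biased are not shown to lack a sex difference. For sex, 4226 genes had an adjusted p under 0.05 (edgeR) and 3162 of these also reached 2-fold. The typical female-biased gene was at a median of 39.5 to 50.9 CPM in egg libraries and 33.5 to 50.9 CPM in female libraries, and at 11.3 to 16.5 CPM in each larval, pupal and male library. Male-biased genes were mostly low in eggs, at medians of 0.42 to 0.66 CPM, and were present in pupae at 15.2 to 22.2 CPM.

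Sex bias was set against the larva to egg and pupa to larva changes in a family of 16 Fisher's exact tests, with Benjamini-Hochberg adjustment. Male-biased genes were higher in larvae than eggs in 59.7% of cases against 30.4% of genes not called sex-biased (odds ratio 3.40, 95% interval 3.06 to 3.78). This rested on larva replicate 1: without it the shares were 27.6% and 29.1% (odds ratio 0.927, 0.826 to 1.04, adjusted p of 0.212 by Fisher's exact test). Both sets were less often lower in pupae than in larvae, with odds ratios of 0.413 (0.352 to 0.482) for male-biased and 0.423 (0.353 to 0.505) for female-biased genes. Male-biased genes had medians of only 0.76 and 0.95 CPM in larva replicates 2 and 3. Many of them therefore had little room to be called lower in pupae. Of the 16 tests, those of male-biased genes and of genes with a female bias of 16-fold or more for being higher in pupae than larvae did not pass, at adjusted p of 0.398 and 0.91. The first of these also rested on larva replicate 1, since without it 65.2% of male-biased genes were higher in pupae against 21.6% of genes not called sex-biased (odds ratio 6.82, 6.11 to 7.63). The last still did not pass, at an adjusted p of 0.428. For genes with a male bias of 16-fold or more, both tests of being higher turned direction without larva replicate 1. The share higher in larvae than eggs went from 67.6% (odds ratio 4.78) to 10.2% (0.275). The share higher in pupae than larvae went from 6.01% (odds ratio 0.239) to 84.4% (19.6). The odds ratios for being lower kept their direction, from 0.0801 to 0.584 in larvae against eggs and from 0.0891 to 0.0848 in pupae against larvae. These genes had medians of 0 CPM in larva replicates 2 and 3 and of 0.07 to 0.16 CPM in eggs. Such levels leave little room to be called lower.

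A candidate explanation for the female-biased genes in eggs is that ovaries and eggs share transcripts. The odds ratio for being higher in eggs was 8.73 (95% interval 7.64 to 9.99) against larvae with all libraries, 8.71 (7.72 to 9.84) without larva replicate 1 with sex bias called again, 8.42 (7.37 to 9.64) without it for the same gene sets, and 7.35 (6.47 to 8.35) against pupae, the last 3 outside the family of 16. These values restate the pattern on the same egg libraries and do not test the explanation, which stays open. Egg libraries carry a column prefix of their own, so a batch shift between eggs and the other stages cannot be told apart from the stage. Whether these transcripts were made in the ovary or in the embryo was not tested.

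Of the 1820 male-biased genes, 88.7% reached 1 CPM in larva replicate 1, against 47.5% and 49.5% in larva replicates 2 and 3, and the gap was wider, 87.3% against 12.8% and 14.9%, for those with a bias of 16-fold or more. The authors' larval list, chosen on these same libraries, took 19.7% of the counts of this library against 17.1% and 16.2% in the other larval libraries. On the TMM scale, RNA of adult males like those sampled would have to make up 57.7% of this library. That would give the median of 398 abundant male-biased genes, a set chosen on adults. Yet 12.3% of those genes lay under 10% of that share, 9 of the 10 most abundant lay under 1% of the adult level, and CAG9854698.1, at 21705 CPM in adult males, had 0 counts, which argues against this source. RNA of pupae like those sampled would need a share of 93.5% on the same scale. Yet 91.3% of 241 abundant pupa-enriched genes lay under 10% of it, which argues against such pupae as the source. The TMM factors were 0.694 for this library, 0.960 to 1.06 for male adults and 0.833 to 0.929 for pupae. As shares of the library's counts, both needed shares would be lower. Pupae or adults unlike those sampled, and mixtures of sources, were not tested. It also stays open whether the larvae in the libraries differed in sex or age, which the labels do not give. If replicate 1 held males and the others did not, strongly female-biased genes could be less often detected in it, but 43.6% were detected in replicate 1 against 35.9% and 40.2% in the others, at medians of 0.70, 0.37 and 0.58 CPM. These levels are too near the floor to decide, and age was not tested.

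In splits of the same libraries, the 3 comparisons of 3 against 3 allow only 10 splits, too few for a share under 0.05. The real split gave the highest count, 1 of the 10 splits, in each: 3162 against at most 0 for female and male adults, 6773 against at most 1 for larva and egg and 4654 against at most 0 for pupa and larva. For adults as 1 group against pupae, 1 of 84 splits reached the real 4060. The next highest, 3389 and 961, set the 3 female and the 3 male adult libraries apart. A split that mixes groups widens the spread within each side and so calls few genes. These splits therefore show that each group stands apart, but they cannot exclude chance. For the specific genes, 100 groupings of the 15 libraries into 5 groups were compared, the real one and otherwise random dealings. The real grouping was the only 1 of the 100 to reach its count for egg-specific (952, highest other 0), pupa-specific (833, highest other 264), male-specific (215, highest other 58) and female-specific genes (96, highest other 0). For larva-specific genes it was 1 of 2 (568, highest other 582). The highest other counts above 0 came from dealings that kept all 3 libraries of 1 group together. Dealings that mix groups widen the spread in the same way, so their low counts cannot exclude chance. The dealing with 582 put the 3 pupal libraries together under the larval label.

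Male adult replicate 2 gave 1.05% of its counts to the authors' pupal list and 0.152% to their larval list, against 0.562% and 0.621%, and 0.719% and 0.564%, in male adult replicates 1 and 3.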
